A study of Zea mays with 32 samples.

How the data were processed

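Leaf RNA of maize (Zea mays) was measured by RNA sequencing after depletion of ribosomal RNA, in B73 wild type (wt) plants and in plants carrying rmr6-1, a mutation of the largest subunit of RNA polymerase IV (nrpd1). Per the labels, the youngest wrapped leaf was taken at the end of 10 days of treatment (T0) or after 7 further days of recovery (T7). Control plants received 75% of disposable water at a salt concentration of 0.1 dS/m, drought plants 25% at 0.1 dS/m, salt plants 75% at 15 dS/m, and drought plus salt plants 25% at 15 dS/m. The 32 libraries fell into 16 groups of genotype, treatment and time with 2 libraries each, replicate 1 and a pool of replicates 2 and 3. Replicate 1 was made with a kit that does not mark the strand and the pool with a stranded kit, per the labels' protocols, and all were sequenced on an Illumina HiSeq instrument. Overlapping and antisense loci therefore could not be told apart with certainty.

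The submitters' processing notes name CASAVA 1.8, cutadapt 1.2rc2, TopHat2 2.0.9, Cufflinks 2.2.0 and Cuffnorm with the genome build B73 RefGen_v3, without saying which of them made which table. The deposited values are FPKM, fragments scaled by transcript length and library size. Each comparison table gives 1 value per side, and another table gives 1 value for each of the 16 conditions, scaled together. The table of all conditions names FPKM in its column names, per the file headers. For the comparison tables the unit was taken from the Cuffdiff layout and the size of the values. The comparison tables also hold the authors' p-value and q-value for each feature, per the file headers, and the authors' mark of the features that passed. Other positions and classes of loci (coding, long noncoding RNA, small RNA precursor, transposable element) came from the annotation the authors deposited. The tables list 114381 gene loci and 160448 transcripts, of which 3927 gene loci were added by the authors. No value per library was analysed here, and the spread between plants is therefore unknown in all fits below.

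Before use, the comparison tables were checked against themselves. In the gene table of rmr6 against wt, 161 called genes shared 1 deposited log2 fold of -2.37 beside different FPKM values, and 160 of them differed by more than 0.01 from the fold of those values. All folds were therefore computed from the FPKM values on both sides. In all gene tables some p-values carried more than 1 q-value, for 92 p-values in the table of wt at T0, so the deposited q was not a single Benjamini-Hochberg adjustment. The authors' mark at q of 0.05 or less was kept as the call. Adjusting the deposited p-values anew gave 1996, 645, 508 and 914 genes for the stress tables of wt T0, rmr6 T0, wt T7 and rmr6 T7 and 1070 for rmr6 against wt. All authors' calls were among them, except that 1056 of the 1059 calls of the genotype table were. The comparison tables were also set against the table of all conditions, with the mean of the 3 stresses there as the stressed value, after the calls had been seen. Among genes at FPKM 1 or more on both sides in both, the control values of the stress tables lay lower than there, by medians of -0.21, -0.29, -0.26 and -0.27 log2 units for wt T0, rmr6 T0, wt T7 and rmr6 T7, and the stressed values lay at 0.06, -0.03, -0.08 and 0.02. In the table of rmr6 against wt, where both sides are controls, the medians were -0.18 for wt and -0.32 for rmr6. The difference varied from gene to gene (5th to 95th percentile -1.07 to 0.39 for the control of wt T0), and its cause was not tested. Read depth was unknown: low FPKM values lay near whole multiples of 1 unit in 22.4% to 25.3% of cases, within a tolerance of 0.1, where chance gives 20%.

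For comparisons of conditions, limma 3.58.1 in R 4.3.3 was run with a mean-variance trend on log2(FPKM + 1) of the condition values, keeping loci at FPKM 1 or more in at least 2 values, with Benjamini-Hochberg adjustment and a threshold of 0.05. The genotype effect used the 8 conditions of treatment and time as blocks, so its residual was the interaction of genotype and condition, not a spread between plants. The 98 loci marked as too deep to estimate in any gene table were left out of the fits. Folds of these fits are on the log2(FPKM + 1) scale, which understates the change of low genes. Fixed before the data were examined were the gene lists, the comparisons of the authors' calls, the genotype effect, the alternatives planned for them and the rule for named genes. The limma fits for stress against control, for single stresses and for differences between stress responses were added afterwards, as were the use of the planned fit of T7 alone as a result of its own, the lists by symbol, the comparison of the authors' tables, folds taken from the median, the fit with loci too deep to estimate, the adjustment anew of the deposited p-values and the fits without loci under 200 bp of exon. The alternatives were a q of 0.01, an absolute log2 fold of 1, higher FPKM filters, the transcript tables, reference loci alone, a pseudocount of 0.1, quantile normalization, no blocks and leaving out each condition in turn.

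The named genes were nrpd1, then among called genes with a symbol and an FPKM of 5 or more on 1 side the 5 largest rises and 5 largest falls, without folds against 0. Up to 4 called members with the highest FPKM followed for each fixed list with at least 2 called members or a passing test, up to about 30 genes per comparison; 1 gene that this rule names and 1 member of a list by symbol are not reported here. Names came from a gene table of the assembly Zm-B73-REFERENCE-NAM-5.0, used for names alone: 18874 of 114381 loci matched a gene, 519 of them more than 1, and 2610 had a usable symbol. Of 124 listed gene identifiers, 5 were left out because that table names them as another gene. The 17 fixed lists covered stress hormones, water and ion transport, protective metabolism, defence compounds, the circadian clock, photosynthesis, flowering and DNA methylation, and lists with under 5 tested members were described and not tested. Another 29 lists were made from symbols after the data were first opened and before the values of their genes were read. Lists and classes were compared with all other tested genes by Fisher's exact test, two-sided, adjusted over lists and directions within a comparison, separately for fixed lists and lists by symbol. The test treats genes as independent. Overlaps of calls were set against n1 × n2 / N, the number given by chance. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 did the rest.

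The fits were tested on simulated data with 200 changed genes. In the data, the genotype effect, rmr6 against wt at T7 and drought at T0 had 12751, 4588 and 2574 genes called. With so many calls the adjustment is less strict, so the simulated shares may understate what these fits recover. For the genotype effect over 38672 genes, 49.0%, 85.0% and 90.0% of genes changed by 0.5, 1 and 2 log2 units were recovered, with 6, 10 and 10 false calls. For the drought effect at T0 over 36335 genes the recovered shares were 0.0%, 49.0% and 81.5%, and for rmr6 against wt at T7 over 36230 genes 0.0%, 40.0% and 82.0%. For the salt effect they were 0.0%, 51.0% and 79.5% at T0 and 0.0%, 52.5% and 81.0% at T7, and for the drought effect at T7 0.0%, 58.0% and 80.5%. For stress against control in wt at T0 they were 0.0%, 26.5% and 65.5%, and for the difference of stress responses between genotypes at T0 they were 0.0%, 2.0% and 49.5% over 38672 genes. The list test over the 37895 genes of the wt T0 table found a list with 50% of its members raised in 74 of 100 draws and called 1 of 800 other lists.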

Results

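The data hold FPKM values of 114381 gene loci in the youngest wrapped leaf of maize, for wt and rmr6-1 plants under control, drought, salt and drought plus salt treatment, at the end of 10 days of treatment (T0) and after 7 days of recovery (T7). Each of the 16 groups had 2 libraries, which the deposited values combine into 1 value per condition, so no error between plants is given for any FPKM below. Between 31496 and 33232 loci reached an FPKM of 1 in a condition. The number of reads per library is unknown from these values, and the 10 highest loci took 32.7% of the summed FPKM in wt Control T0 and 49.7% in rmr6 Drought+Salt T0. The authors compared the 3 stresses together with the control of the same genotype and time, and rmr6 control plants with wt control plants at T0. These comparisons ask how leaves respond to water and salt stress, how much of the response remains after recovery, and what the loss of RNA polymerase IV changes.

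The targeted gene nrpd1 (GRMZM2G007681, chromosome 1, 188750733 to 188845320 in B73 RefGen_v3), which encodes the largest subunit of RNA polymerase IV, was lower in rmr6 than in wt in all 8 conditions. Its mean was 4.50 FPKM in wt and 3.07 FPKM in rmr6. The limma fit over the 8 conditions gave a log2 fold of -0.44 (SE 0.0531, adjusted p = 0.000372). In the authors' deposited table of T0 controls it was at 4.93 FPKM in wt and 2.35 in rmr6, a log2 fold of -1.07 with q = 0.256, which did not pass. The labels do not say that rmr6-1 lowers the transcript, so this level does not check the genotype labels.

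**Figure D1:**
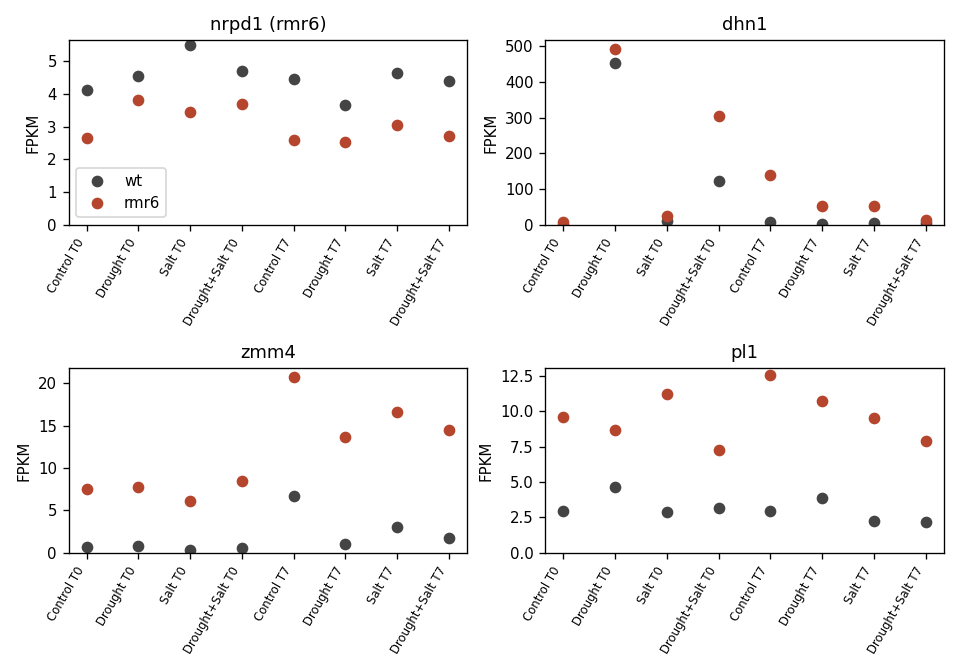
FPKM of nrpd1, dhn1, zmm4 and pl1 (vertical axes) in each of the 8 conditions of treatment and time (horizontal axes), 1 point per genotype and condition and no error bars because the deposited values combine the libraries. For nrpd1 the rmr6 point lies under the wt point in all 8 conditions, with means of 3.07 and 4.50.

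In wt leaves at T0, genes of benzoxazinoid synthesis, jasmonate, the clock and abscisic acid rose under stress and few genes were called lower. The dehydrin gene dhn1/rab17 (GRMZM2G079440), which is induced by abscisic acid, rose from 0.452 to 138 FPKM in the authors' deposited table, a log2 fold of 8.25 (q = 0.00268). At the same q, phytase2 rose by 4.64 log2 units, the alkaline alpha-galactosidase gene AGA1 by 4.40 to 113 FPKM, the glutathione transferase gene GST25 by 3.83 and p5cs2, which encodes an enzyme of proline synthesis, by 3.61 to 41.4 FPKM, per the authors' deposited table. The largest falls among named genes of the authors' deposited table were those of Actin-7 (log2 fold -1.49), the aquaporin gene pip2-4 (-1.04), the kinesin gene KIN13 (7.22 to 3.60 FPKM), the tubulin gene tua5 (-0.94) and psiP (-0.90). In all, 1908 genes were called higher and 75 lower among 37895 tested in the authors' deposited table. The median log2 fold of genes at FPKM 1 or more on both sides in that authors' deposited table was 0.27. By limma, with the 3 stresses as replicates against the control value, 23 genes passed (3607 at unadjusted p under 0.05), 4 higher and 19 lower, and 0 passed without loci under 200 bp (3545 unadjusted). That test was chosen after the authors' calls had been seen. In simulated data it recovered 26.5% of changes of 1 log2 unit and 65.5% of 2 log2 units, and why it passed so few genes here was not tested. The authors' table of all conditions, set beside the comparison tables after the calls had been seen, had another balance of directions. Among 28270 genes at FPKM 1 or more on both sides in both tables it had 931 rises of 2-fold or more and 798 such falls, where the comparison table had 2267 and 414. With genes at FPKM 1 or more on either side and a pseudocount of 1, rises were 63.1% of 2-fold differences there and 82.4% in the comparison table. Of the genes called higher 1877 were higher there too, 864 of them by 2-fold or more, and of those called lower 75 and 67. Of the 75 called lower, 35 were at an FPKM of 0 under stress in the comparison table. For 14 of 29 named genes called in wt at T0 the folds of the tables differed by over 1.5 times.

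Benzoxazinoid synthesis, the route to the defence compounds of young maize, rose in wt at T0, with 8 of 13 members called higher and none lower (Fisher's exact test, adjusted p = 7.51e-07; 9 adjusted over the list alone). In the authors' deposited table bx6 went from 57.8 to 188 FPKM, bx5 from 35.1 to 88.4, bx3 from 20.0 to 72.8 and bx9 rose by 1.03 log2 units. The table of all conditions gave smaller rises, for bx6 from 94.0 to 204 FPKM, bx5 from 57.4 to 89.9, bx3 from 40.6 to 84.2 and bx9 by a log2 fold of 0.23 from 59.8 FPKM. Of the lipoxygenase and jasmonate genes 7 of 10 rose (adjusted p = 7.66e-07 by Fisher's exact test; 8 adjusted over the list alone). The authors' deposited table gave log2 folds of 1.75 for lox1, 1.35 for lox5 and 1.76 for lox8/ts1, and the table of all conditions 1.08, 0.70 and 0.91. Clock genes rose in 5 of 10 cases (adjusted p = 3.93e-04 by Fisher's exact test; 6 adjusted over the list alone), among them gi2 by 1.46, prr95 by 0.96, prr59 by 1.15 and toc1b by 2.37 log2 units in the authors' deposited table. The hour of harvest is not given in the sources used here. Of 5 tested genes of abscisic acid metabolism and signalling 3 rose (adjusted p = 0.00531 by Fisher's exact test; 4 adjusted over the list alone). These were zep1 (log2 fold 1.01) and vp14/nced1 (3.08), which act in its synthesis, and abh2 (2.05), in the authors' deposited table, with 0.67, 2.02 and 1.21 in the table of all conditions. There abh2 was lower under salt than in the control. The rise of vp14/nced1 there came with drought: it was at 1.85 FPKM in the control, 15.7 under drought, 1.98 under salt and 4.87 under drought plus salt. Among 6 aquaporins pip1-5 (1.21) and pip2-6 (1.64) rose and pip2-4 fell in the authors' deposited table. In the table of all conditions pip1-5 rose by 0.59 and pip2-6 by 0.58, from 4.98 FPKM to 11.3 under drought and 8.02 under drought plus salt, with 3.07 under salt. The test of the falls gave an adjusted p of 0.0425 by Fisher's exact test from that 1 gene, and 4 passed adjusted over the list alone. The falls did not pass against genes at FPKM 5 or more (adjusted p = 0.0544 by Fisher's exact test). Benzoxazinoid (adjusted p = 1.05e-07), lipoxygenase and jasmonate (6.82e-07) and clock genes (0.0166) passed Fisher's exact test there, and the abscisic acid list had under 5 members there and was not tested. With only those calls whose change in the table of all conditions was 2-fold or more, the fixed lists that passed Fisher's exact test in wt at T0 still did. Benzoxazinoid synthesis had 4 higher (adjusted p = 0.001465), lipoxygenase and jasmonate genes 3 (0.00754), the clock 4 (9.09e-04) and abscisic acid 2 (0.0223), and the aquaporin falls gave 0.0380, all by Fisher's exact test.

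Of the remaining fixed lists in wt at T0, sucrose and starch metabolism had 2 of 5 members higher (adjusted p = 0.0687 by Fisher's exact test; 3 adjusted over the list alone), sus2 at 2.08 and ivr1 at 1.46 log2 units in the authors' deposited table (1.16 and 0.89 in the table of all conditions). Anthocyanin synthesis had 2 of 8 higher (adjusted p = 0.130 by Fisher's exact test; 4 adjusted over the list alone). No gene was called among 15 of DNA methylation and 10 of the C4 cycle and Rubisco (adjusted p = 1 in both directions by Fisher's exact test; 0 adjusted over each list alone). Lists too small to test held 1 dehydrin gene, called higher, 2 heat shock genes with none called (2 adjusted over the list alone), 2 genes of proline and related synthesis with 1 higher (1 adjusted over the list alone) and 4 antioxidant genes with 2 higher (3 adjusted over the list alone). They also held 3 nitrogen genes and 4 flowering genes with none called (0 adjusted over each list alone), while sodium and potassium transport and the KNOX genes had 0 tested members. Among lists made by symbol, which share the lipoxygenases with the fixed list, jasmonate synthesis with the TIFY repressors had 22 of 41 members higher (adjusted p = 1.25e-16 by Fisher's exact test). Genes for abscisic acid receptors, PP2C phosphatases and SnRK2 kinases were higher in 11 of 38 cases (adjusted p = 4.54e-05 by Fisher's exact test), with PP2C4 at 41.7 FPKM under stress and 10.1 in the control and PP2C20 at 39.2 and 8.26 in the authors' deposited table (40.7 and 18.9 in the table of all conditions). By the same Fisher's exact test WRKY factors were higher in 5 of 15 cases (adjusted p = 0.0110), glutathione transferases in 6 of 27 (0.0213), potassium and sodium carriers in 5 of 19 (0.0213), heat shock genes in 5 of 23 (0.0329), aquaporins in 5 of 23 (0.0329), terpene synthases in 4 of 16 (0.0414) and sucrose and starch enzymes in 3 of 9 (0.0443). Against genes at FPKM 5 or more, the aquaporins (0.0376), the jasmonate list (8.37e-15) and the abscisic acid list (0.00163) still passed Fisher's exact test. The WRKY factors (adjusted p = 0.274), glutathione transferases (0.230), potassium and sodium carriers (0.488), heat shock genes (0.274), terpene synthases (0.271) and sucrose and starch enzymes (0.274) did not pass it there. With calls at 2-fold in the table of all conditions, the jasmonate list (10 higher, adjusted p = 1.11e-06), the abscisic acid list (7, 5.54e-04) and glutathione transferases (5), WRKY factors (4) and terpene synthases (4, each 0.00408) passed Fisher's exact test. Heat shock genes and aquaporins (2 each, adjusted p = 0.384), carriers (3, 0.05665) and sucrose and starch enzymes (1, 0.573) did not pass it. Examples in the authors' deposited table were the aquaporin gene TIP4-1, from 4.79 to 50.6 FPKM, and the terpene synthase gene tps10, from 2.30 to 20.7. A list of cell cycle, replication and histone genes had 2 lower of 37 (adjusted p = 0.0213 by Fisher's exact test), MCM6 and KIN13, of which KIN13 is a kinesin gene. Without 7 kinesins matched by their symbols it did not pass (adjusted p = 0.188 by Fisher's exact test). Small RNA precursors made up 5.29% of the genes called higher and 12.1% of those tested (adjusted p = 3.58e-24 by Fisher's exact test), and 81 of the 864 that reached 2-fold in the table of all conditions (p = 0.0113 by Fisher's exact test). The comparison table had a control FPKM of 0 for 119 of the genes called higher, where a ratio limit is easily passed. The share among the 864 may therefore reflect that limit, which was not tested.

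**Figure D2:**
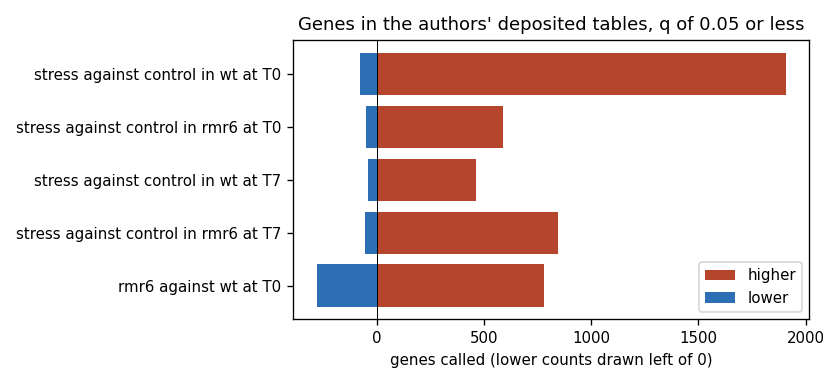
Genes called at q of 0.05 or less in the 5 gene tables of the authors, as the number higher (bars right of 0) and lower (bars left of 0) on the horizontal axis. The table of wt at T0 has 1908 higher and 75 lower, and that of rmr6 against wt at T0 780 higher and 279 lower.

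In rmr6 leaves at T0, clock genes, genes of pathogenesis-related proteins and chitinases, and the dehydrin gene dhn1 rose under stress. The gene dhn1/rab17 rose from 5.64 to 222 FPKM (log2 fold 5.30) and AGA1 from 14.6 to 192 (3.72) in the authors' deposited table, both with q = 0.00713. At the same q the clock gene toc1b rose by 3.23, ys1, which encodes an iron-phytosiderophore transporter, by 3.17 and the chitinase gene chiA by 2.75 log2 units in the authors' deposited table. The rise of ys1 rested mainly on salt: in the table of all conditions it was at 1.36 FPKM in the control, 0.887 under drought, 35.0 under salt and 3.67 under drought plus salt. The gene chiA rose by 1.36 log2 units there. Only calmodulin (GRMZM2G444621; log2 fold -1.66) and Actin-7 (-1.11) met the rule for falls in the authors' deposited table. There were 588 genes called higher and 48 lower among 37935 tested in the authors' deposited table, whose median log2 fold was 0.29. By limma on the condition values 30 genes passed (3614 at unadjusted p under 0.05), 11 higher and 19 lower, and 0 without loci under 200 bp (3419 unadjusted). In the table of all conditions 586 of the genes called higher were higher, 417 by 2-fold or more, and all 48 called lower fell by 2-fold or more. Of these 48, 34 were at an FPKM of 0 under stress in the comparison table, where a ratio limit is easily passed. Small RNA precursors were 82 of the genes called higher (adjusted p = 0.628 by Fisher's exact test against 12.8% of those tested) but 78 of the 417 (p = 6.58e-04 by Fisher's exact test), more than among tested genes. The comparison table had a control FPKM of 0 for 112 of the genes called higher, where a ratio limit is easily passed too. The share among the 417 may therefore reflect that limit, which was not tested. The folds differed by over 1.5 times for 2 of 15 named genes, chiA and bx2. Over 28880 genes the table of all conditions had 816 rises and 925 falls of 2-fold or more, against 1673 and 549 in the comparison table.

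Clock genes rose in 4 of 10 cases in rmr6 at T0 (Fisher's exact test, adjusted p = 1.78e-04; 6 adjusted over the list alone), toc1b together with gi2 (log2 fold 1.45), prr59 (1.39) and toc1a (0.958 to 3.04 FPKM) in the authors' deposited table. Benzoxazinoid genes rose in 3 of 13 cases (adjusted p = 0.00755 by Fisher's exact test; 5 adjusted over the list alone). In the authors' deposited table bx1 went from 4.00 to 24.1 FPKM, bx2 from 4.40 to 17.4 and bx3 from 22.3 to 52.8. The lipoxygenases lox11 (1.29) and lox3 (2.13) rose in the authors' deposited table, 2 of 10 on the list (adjusted p = 0.0530 by Fisher's exact test; 3 adjusted over the list alone). Aquaporins had 0 of 6 called, anthocyanin synthesis 0 of 8, sucrose and starch metabolism 0 of 6, DNA methylation 0 of 15 and the C4 cycle 0 of 10 (adjusted p = 1 by Fisher's exact test; 1, 0, 1, 0 and 0 adjusted over the list alone). Of the lists by symbol, 4 of 9 genes of pathogenesis-related proteins and chitinases rose (adjusted p = 3.52e-04 by Fisher's exact test), PR-5 from 5.33 to 22.9 FPKM and PR-1 from 1.39 to 7.72 in the authors' deposited table. Abscisic acid signalling had 6 of 38 higher (adjusted p = 6.37e-04) and heat shock genes 4 of 23 (0.00694, both by Fisher's exact test), hsp18f among them with a log2 fold of 1.89 in the authors' deposited table. The heat shock list did not pass against genes at FPKM 5 or more (adjusted p = 0.285 by Fisher's exact test). With calls at 2-fold in the table of all conditions, Fisher's exact test passed the clock (4 higher, adjusted p = 4.59e-05), pathogenesis-related proteins and chitinases (4, 9.03e-05) and heat shock genes (4, 0.00281), but not benzoxazinoid synthesis (2, 0.0694) or abscisic acid signalling (2, 0.486).

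The 2 genotypes shared 357 genes called higher at T0, where chance gave 26.7 from 1832 and 512 calls among 35077 genes tested in both (Fisher's exact test, odds ratio 51.7). These comparisons share no libraries. Of calls at 2-fold in the table of all conditions the genotypes shared 215 (7.84 by chance; p = 1.09e-270 by Fisher's exact test). They shared 4 genes called lower, against 0.0291 by chance (p = 1.89e-08 by Fisher's exact test). A call in 1 genotype and not in the other is no test of a difference between them.

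In wt leaves at T7, genes of heat shock proteins were above the control after recovery, over the 3 stresses together. The gene hsp18f was at 11.4 FPKM and 2.39 in the control (log2 fold 2.26, q = 0.0267) and hsp101 at 7.54 and 1.81 (2.06, q = 0.0115) in the authors' deposited table. WRKY104 (2.06), GATA28 (2.05) and the catalase gene cat2 (2.04) were the other named rises of the authors' deposited table, and no fall met the rule. The table of all conditions gave smaller rises, of 0.93 log2 units for hsp18f (from 7.32 FPKM), 0.81 for hsp101 (4.50 to 7.89), 1.32 for WRKY104, 0.36 for GATA28 (6.94 to 8.89) and 1.49 for cat2. All but that of cat2 differed by over 1.5 times. There hsp18f and hsp101 were near the control after drought (7.42 and 4.80 FPKM). They were highest after salt (19.8 and 11.9), with 14.7 and 7.01 after drought plus salt. In the same table the wt control at T0 had 19.6 and 10.1 FPKM, above the 7.32 and 4.50 of the T7 control. The rises at T7 therefore rest on 1 control value that was lower than the control at T0. Of the genes called higher 453 were higher there and 112 by 2-fold or more, and all 40 called lower fell by 2-fold or more. Of these 40, 33 were at an FPKM of 0 in formerly stressed plants in the comparison table, where a ratio limit is easily passed. Small RNA precursors were 3.68% of the genes called higher and 11.5% of those tested (adjusted p = 1.12e-08), and 15 of the 112 (p = 0.552, both by Fisher's exact test). The comparison table had a control FPKM of 0 for 50 of the genes called higher, so the share among the 112 may reflect the ratio limit. Over 28061 genes the table of all conditions had 413 rises and 529 falls of 2-fold or more, against 1816 and 544 in the comparison table. In all, 462 genes were called higher and 40 lower among 35821 tested in the authors' deposited table, with a median log2 fold of 0.20. At q of 0.01 the authors' deposited table had 0 calls, with 3462 genes at unadjusted p under 0.05, and limma on the condition values passed 15 (1418 unadjusted), 1 higher and 14 lower. Of the fixed lists none passed Fisher's exact test: 1 of 13 benzoxazinoid genes was called (adjusted p = 1; 6 adjusted over the list alone), 1 of 10 lipoxygenase genes (1 adjusted over the list alone), and 0 of 7 aquaporins (3 adjusted over the list alone). Clock genes had 0 of 10 called (0 adjusted over the list alone). Among lists by symbol 6 of 21 heat shock genes were higher (adjusted p = 1.07e-05 by Fisher's exact test), with Hsp70 from 19.1 to 55.7 FPKM and hsp22 from 9.35 to 36.1 in the authors' deposited table. The table of all conditions had Hsp70 at 42.5 and 57.9 FPKM and hsp22 at 17.2 and 39.7. With calls at 2-fold in the table of all conditions, heat shock genes were higher in 3 cases (adjusted p = 0.00198 by Fisher's exact test).

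In rmr6 leaves at T7, genes of jasmonate signalling were higher in formerly stressed plants than in the control, by folds that differed widely between the authors' tables. The jasmonate repressor genes TIFY20 (log2 fold 3.73), TIFY10 (3.65), TIFY4 (2.96, to 89.3 FPKM) and TIFY9 (2.91) led the rises of the authors' deposited table. All had q = 0.0117 in the authors' deposited table. OBAP1A, which encodes an oil body protein, rose by 2.84 in the authors' deposited table, the ascorbate peroxidase gene apx2 from 49.8 to 119 FPKM and cat2 from 3.34 to 9.86. For all 14 named genes called here the table of all conditions gave a smaller rise, by over 1.5 times. It had TIFY20 at a log2 fold of 1.44, TIFY10 from 3.82 to 9.38 FPKM, TIFY4 at 0.66 (54.1 to 85.2 FPKM) and TIFY9 at 1.02. Further values there were OBAP1A at 0.62 (from 2.61 FPKM), apx2 at 0.36 (89.9 to 115) and cat2 at 0.32 (from 8.79 FPKM). There OBAP1A was lower than the control under salt (2.57 FPKM) and cat2 under drought plus salt (6.48). There were 845 genes called higher and 54 lower among 39517 tested in the authors' deposited table, with a median log2 fold of 0.30. Of the genes called higher 760 were higher in the table of all conditions and 238 by 2-fold or more, and all 54 called lower fell by 2-fold or more. Of these 54, 49 were at an FPKM of 0 in formerly stressed plants in the comparison table, where a ratio limit is easily passed. Small RNA precursors were 6.04% of the genes called higher, under the 12.5% of those tested (adjusted p = 2.57e-09 by Fisher's exact test), but 42 of the 238, above it (p = 0.0232 by Fisher's exact test). The comparison table had a control FPKM of 0 for 164 of the genes called higher, where a ratio limit is easily passed. The share among the 238 may therefore reflect that limit, which was not tested. Over 29161 genes the table of all conditions had 381 rises and 698 falls of 2-fold or more, against 2172 and 608 in the comparison table. By limma on the condition values 31 genes passed (1530 at unadjusted p under 0.05), 15 higher and 16 lower.

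Lipoxygenase and jasmonate genes rose in 3 of 10 cases in rmr6 at T7 (Fisher's exact test, adjusted p = 0.0209; 6 adjusted over the list alone), lox8/ts1 by 1.35, lox11 by 1.36 and lox3 by 2.50 log2 units in the authors' deposited table (0.69, 0.13 and 0.07 in the table of all conditions). There lox3 was lower than the control under drought and under drought plus salt. This list did not pass against genes at FPKM 5 or more (adjusted p = 0.124 by Fisher's exact test). The aquaporin genes pip2-6 (1.27) and pip2-4 (1.41) rose in the authors' deposited table, 2 of 7 listed (adjusted p = 0.0893 by Fisher's exact test; 4 adjusted over the list alone). They rose by 0.67 and 0.64 in the table of all conditions, where pip2-6 was lower than the control under drought plus salt. Benzoxazinoid genes had 2 of 13 called (adjusted p = 0.203 by Fisher's exact test; 9 adjusted over the list alone), bx1 (log2 fold 1.18) and bx12 (0.769 to 3.60 FPKM) in the authors' deposited table. In the table of all conditions bx1 rose by 0.28, with a fall under drought plus salt, and bx12 by 1.21. Among lists by symbol, jasmonate synthesis with the TIFY repressors had 12 of 41 higher (adjusted p = 2.04e-09), heat shock genes 8 of 23 (4.21e-07) and ethylene-responsive factors 8 of 29 (2.20e-06, all by Fisher's exact test). EREB92 rose from 6.74 to 22.1 FPKM and Hsp70 from 19.0 to 64.1 in the authors' deposited table, and from 13.4 to 18.9 and from 44.3 to 71.4 in the table of all conditions. Glutathione transferases were higher in 4 of 28 cases (0.0381), and WRKY factors in 3 of 16, bHLH factors in 4 of 33 and terpene synthases in 3 of 17 (each with an adjusted p of 0.0409 by Fisher's exact test). Against genes at FPKM 5 or more the ethylene-responsive factors (adjusted p = 0.274), glutathione transferases (0.333), WRKY (0.163) and bHLH factors (0.28) and terpene synthases (0.274) did not pass Fisher's exact test, while the jasmonate and heat shock lists did. With calls at 2-fold in the table of all conditions the jasmonate list alone passed Fisher's exact test (4 higher, adjusted p = 0.00589). Heat shock genes (1 higher), ethylene-responsive factors (2, adjusted p = 0.304) and the fixed list of lipoxygenases (0) did not. At T7 the genotypes shared 130 genes called higher, against 9.72 by chance (p = 8.88e-109 by Fisher's exact test). Between T0 and T7, 124 genes called higher were shared in wt (22.8 by chance; p = 2.95e-56) and 77 in rmr6 (11.3 by chance; p = 1.03e-40, both by Fisher's exact test). Of calls at 2-fold in the table of all conditions these pairs shared 8 (0.437 by chance; p = 1.47e-08), 26 (2.11; p = 3.06e-21) and 12 (1.75; p = 2.24e-07, all by Fisher's exact test).

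Among unstressed plants at T0, glucA, zmm4 and TPS4 were the named genes with the largest rises in rmr6, and small RNA precursors were frequent among the genes called higher. The gene glucA rose from 0.346 to 10.7 FPKM (log2 fold 4.95), zmm4, a MADS-box gene of the floral transition, from 0.497 to 5.26 (3.40) and the terpene synthase gene TPS4 from 1.09 to 6.40 (2.55) in the authors' deposited table, each with q = 0.00355. At the same q cpi2 (2.47), AAMT2, which encodes an anthranilic acid methyltransferase (2.44), the pigment regulator pl1 (2.39) and pr1 of flavonoid hydroxylation (1.83) were higher in rmr6 in the authors' deposited table. The falls of bHLH30 (log2 fold -1.70), an actin gene (GRMZM2G006765, -1.67), the histone H2B gene his2b5 (-1.65) and KIN13 (-1.54) were among the largest of the authors' deposited table by the rule. In all 780 genes were higher and 279 lower among 38566 tested in the authors' deposited table, with a median log2 fold of -0.18, and 492 of the called genes were listed at 0 in wt. In the table of all conditions 779 of the genes called higher were higher, 761 by 2-fold or more, and all 279 called lower were lower, 241 by 2-fold or more. Of the 780 called higher, only 146 were at FPKM 1 or more on both sides in both tables. From a value of 0 in wt a ratio limit is easily passed. For 5 of 12 named genes the folds differed by over 1.5 times. They were 4.11 for glucA, 1.70 for pl1, 0.85 for pr1, -0.89 for his2b5 and -0.77 for KIN13 there. No fixed list passed Fisher's exact test: anthocyanin synthesis had 2 of 8 higher (adjusted p = 0.169; 2 adjusted over the list alone), DNA methylation 0 of 15 (0 adjusted over the list alone) and benzoxazinoid synthesis 0 of 13 (0 adjusted over the list alone). Cell cycle, replication and histone genes, a list by symbol, were lower in 4 of 36 cases (adjusted p = 0.00684 by Fisher's exact test), namely his2b5, MCM6, Rbl1 and the kinesin gene KIN13. Without 7 kinesins the list did not pass (adjusted p = 0.0619 by Fisher's exact test). With them it did not pass against genes at FPKM 5 or more (adjusted p = 0.302 by Fisher's exact test) or with calls at 2-fold in the table of all conditions, of which it held 1.

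Small RNA precursors were more frequent among genes higher in rmr6 at T0, 198 of 780 or 25.4%, than among tested genes, of which 12.9% were precursors (adjusted p = 2.01e-20 by Fisher's exact test). Loci the authors added to the annotation made up 29.2% of them and 7.94% of tested genes (adjusted p = 3.00e-69 by Fisher's exact test). Antisense loci were 15 of the genes higher in rmr6 (adjusted p = 0.0402 by Fisher's exact test), and they cannot be told apart from their partners with certainty. In this comparison 492 of the genes called higher were at 0 in wt. Whether the shares of these classes reflect values near 0 was not tested. The calls of this table gathered on chromosome 1: the 10 Mb from 180000001 to 190000000, which hold nrpd1, had 27 of 225 tested genes called, 16 higher and 11 lower (odds ratio 4.88, p = 2.03e-10 by Fisher's exact test), against 2.77% elsewhere. From 200000001 to 210000000 it was 18 of 201 (8.96%; adjusted p = 0.00148 by Fisher's exact test). The genes called higher in this table included 114 that also rose under stress in wt at T0 (12.1 by chance; p = 6.13e-81 by Fisher's exact test) and 46 that rose under stress in rmr6 at T0 (9.77 by chance; odds ratio 5.38, p = 4.37e-18 by Fisher's exact test). The genes called lower included 14 that rose under stress in rmr6 at T0 (2.86 by chance; odds ratio 5.29, p = 1.315e-06 by Fisher's exact test). They also included 12 that fell under stress in wt at T0 (0.577 by chance) and 4 that rose there (13.1 by chance; p = 0.00621 by Fisher's exact test). Both pairs share a control. In the first pair it is the lower side of both comparisons, which raises the overlap, so part of the excess may come from the shared control. In the pair with rmr6 it is the lower side of the stress comparison and the second side of the other, which raises the overlap of 14 and reduces that of 46. For genes higher in both comparisons the overlaps of calls at 2-fold in the table of all conditions were 76 (4.46 by chance) in the first pair and 32 (6.11 by chance) in the pair with rmr6.

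**Figure D3:**
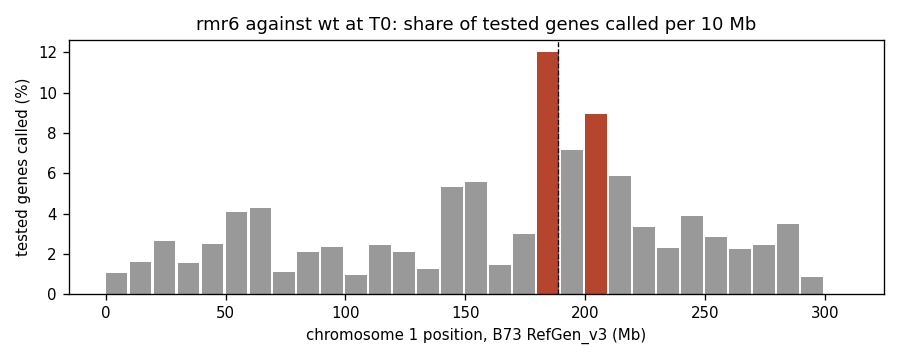
Share of tested genes called in rmr6 against wt at T0 (vertical axis, percent) for each 10 Mb of chromosome 1 (horizontal axis, Mb in B73 RefGen_v3), with the position of nrpd1 as a dashed line. The intervals that passed the test, drawn in red, hold 27 of 225 and 18 of 201 tested genes.

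Over all 8 conditions the limma fit gave higher levels of pathogenesis-related and chitinase genes and lower levels of genes of ribosomal proteins, expansins and cellulose synthases in rmr6. The largest named rises were those of gst18 (log2 fold 2.76, SE 0.170, adjusted p = 7.24e-06), cpi2 (2.64, SE 0.194), glucA (2.57, SE 0.128), HSP90-1 (2.38, SE 0.219) and AAMT2 (2.36, SE 0.173), each of limma. The mean of HSP90-1 was 39.0 FPKM in wt and 183 in rmr6, and the gene lies at 184272689 to 184277348 of chromosome 1, inside the interval where calls gathered. The largest named falls were those of CYP92C5 (-1.44, SE 0.241), eks1, which encodes an ent-kaurene synthase (-1.35, SE 0.205), In2-1 (-1.10, SE 0.209), mads1 (-1.06, SE 0.0757) and Myb36 (-1.05, SE 0.0830). Of 38672 genes 5790 were higher and 6961 lower in rmr6, and with quantile normalization 5092 were higher and 8639 lower. The residual of this fit is the interaction of genotype and condition, not a spread between plants, and 1 line of each genotype was compared. Leaving out 1 condition in turn kept the direction and an unadjusted p under 0.05 for 12489 of the 12751 genes, and for 30 of 30 named genes. In all 8 of these fits 9280 of the genes and 25 of the named genes passed the adjusted threshold. The genes had been chosen from the same values at a stricter threshold, so the check at unadjusted p could hardly fail.

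No fixed list passed Fisher's exact test for the genotype effect. Aquaporins had 5 of 7 lower and 1 higher (adjusted p for lower 0.0516; 6 adjusted over the list alone), with pip1-1 at 431 FPKM in wt and 329.6 in rmr6 and pip1-5 at 22.6 and 11.5. The C4 cycle and Rubisco had 4 of 10 lower (adjusted p = 0.397 by Fisher's exact test; 6 adjusted over the list alone), ssu2 (-0.33), pep1 (-0.44), rca1 (-0.27) and ssu1 (-0.41). Anthocyanin synthesis had 4 of 8 lower and 1 higher (adjusted p for lower 0.238 by Fisher's exact test; 5 adjusted over the list alone): the chalcone synthase genes c2 (-0.45) and whp1 (-0.45) fell and the regulator pl1 rose by 1.38 (SE 0.117). Of 5 flowering genes 3 rose and 1 fell (adjusted p for higher 0.238 by Fisher's exact test; 5 adjusted over the list alone), zmm4 by 2.34 (SE 0.133), the florigen gene zcn8 by 0.86 (SE 0.179) and zap1 by 0.78 (SE 0.157). The clock genes gi1 (0.22), gi2 (0.26) and prr59 (0.31) rose, 3 of 10 (adjusted p = 0.645 by Fisher's exact test; 3 adjusted over the list alone). In DNA methylation 2 rose and 1, nrpd1 itself, fell of 15 (adjusted p for higher 1 by Fisher's exact test; 3 adjusted over the list alone). Benzoxazinoid synthesis had 1 higher and 1 lower of 13 (1 adjusted over the list alone), sucrose and starch metabolism 1 higher and 1 lower of 6 (3 adjusted over the list alone), and lipoxygenase and jasmonate genes 2 lower of 10 (1 adjusted over the list alone), lox5 by -0.93 log2 units (SE 0.109).

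Of the lists by symbol, 22 of 36 ribosomal protein genes were lower in rmr6 (adjusted p = 5.72e-07 by Fisher's exact test), rpl19 by -0.41 (SE 0.0465) log2 units. Expansins and cellulose synthases were lower in 15 of 27 cases (adjusted p = 2.22e-04), bHLH factors in 14 of 31 (0.00579), aquaporins in 11 of 24 (0.0163) and glutathione transferases in 11 of 26 (0.0296, all by Fisher's exact test). The glutathione transferases did not pass against genes at FPKM 5 or more (adjusted p = 0.166 by Fisher's exact test), while the ribosomal, expansin, bHLH and aquaporin lists did. The expansin gene expB6 fell by 0.40 (SE 0.0759) on the log2 scale. Pathogenesis-related proteins and chitinases were higher in 7 of 8 cases (adjusted p = 2.22e-04 by Fisher's exact test), PR-5 by 1.48 (SE 0.339), a chitinase gene (GRMZM2G453805) by 1.18 (SE 0.184) and chiA by 0.76 (SE 0.129). Small RNA precursors were 1120 of the 5790 genes higher in rmr6 (19.3%), against 11.9% of those tested (adjusted p = 1.31e-71 by Fisher's exact test). This fit and the authors' table of T0 controls shared 653 genes higher in rmr6 (108 by chance). The fit includes the libraries of that table.

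After recovery, at T7, dhn1/rab17 was higher in rmr6 than in wt, at a mean of 65.3 FPKM against 5.22 (limma, log2 fold 3.18, SE 0.632, adjusted p = 0.0428), with 140 FPKM in the rmr6 control. The genes AAMT2 (2.57, SE 0.207), gst18 (2.54, SE 0.157), cpi2 (2.51, SE 0.251) and glucA (2.37, SE 0.170) rose as well, and nrpd1 fell by 0.50 (SE 0.0661, adjusted p = 0.0166 by limma) on the log2 scale. Lower in rmr6 were mads1 (from 9.96 to 3.58 FPKM, SE of the log2 fold 0.0553), Myb36 (-1.08, SE 0.119), pOMT1 (-1.03, SE 0.120), the jasmonate repressor TIFY27 (-0.99, SE 0.0729) and Agpat4 (-0.98, SE 0.0637). Flowering genes were higher in 3 and lower in 1 of 5 cases (adjusted p for higher 0.0535 by Fisher's exact test; 5 adjusted over the list alone), zmm4 by 2.26 (SE 0.242), mads15/zmm15 by 1.94 (SE 0.190) and zap1 by 1.15 (SE 0.147). The sucrose synthase gene sus1 was lower (-0.50, SE 0.0823) and sps1 of sucrose synthesis higher (1.84, SE 0.275), 2 of 6 on their list (2 adjusted over the list alone). In benzoxazinoid synthesis bx1 (1.46, SE 0.225) and bx3 (0.69, SE 0.127) rose and igl1 (-0.53, SE 0.0835) fell, 3 of 13 (3 adjusted over the list alone). The DNA methyltransferase gene dmt103/zmet3 rose by 0.53 (SE 0.0552), 1 of 15 on its list with nrpd1 itself lower (2 adjusted over the list alone). No fixed list and no list by symbol passed Fisher's exact test. Of 36230 genes 2506 were higher and 2082 lower, and with quantile normalization 2032 and 2495. This fit was planned as an alternative of the genotype effect, and its use as a result of its own was chosen after the data were seen, since the authors' tables hold no such comparison. The count was 1432 without the control pair, 1293 without the drought pair, 2025 without the salt pair and 1815 without the drought plus salt pair, and 8 of 22 named genes passed in all 4. Small RNA precursors were 23.6% of the genes higher in rmr6 and 11.5% of those tested (adjusted p = 5.96e-69 by Fisher's exact test).

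Drought at T0, with or without salt and over both genotypes, went with higher levels of heat shock genes and genes of abscisic acid signalling. By limma dhn1/rab17 rose by 5.16 (SE 0.746, adjusted p = 0.0280), AGA1 by 3.10 (SE 0.508), the asparagine synthetase gene asn3 by 2.29 (SE 0.263), mtl2 by 2.28 (SE 0.260) and hsp 17.2 by 2.24 (SE 0.237). The largest named falls were those of calmodulin (-1.64, SE 0.249), nfd106 (-1.41, SE 0.229), the replication gene pcna2 (-1.31, SE 0.120), vignain (-1.28, SE 0.208) and RNRS3 (-1.25, SE 0.135), which encodes a ribonucleotide reductase subunit. In sucrose metabolism sus1 fell from a mean of 625 to 282 FPKM (-1.12, SE 0.140) and sus2 rose from 5.91 to 13.8 (1.11, SE 0.0893). The Rubisco genes ssu2 (-0.68, SE 0.104) and ssu1 (-0.52, SE 0.102) fell, 2 of 10 on the list of the C4 cycle (adjusted p = 1 by Fisher's exact test; 3 adjusted over the list alone), and no fixed list passed. Of 36335 genes 1047 were higher and 1527 lower, a fit chosen after the data were seen. This count depended on every condition: it was 15 without wt Control, 3 without wt Drought, 7 without wt Salt, 561 without wt Drought+Salt, 14 without rmr6 Control, 1 without rmr6 Drought, 4 without rmr6 Salt and 2 without rmr6 Drought+Salt. The direction and an unadjusted p under 0.05 held in all 8 of these fits for 2568 of the 2574 genes and for 14 of 14 named genes, while 0 of the named genes passed the adjusted threshold in all. The check at unadjusted p could hardly fail, because the genes had been chosen from the same values at a stricter threshold. Without loci under 200 bp, a setting also chosen afterwards, 4342 genes passed. With a condition left out as well, 823 did without wt Control, 1249 without wt Drought, 1961 without wt Salt, 3088 without wt Drought+Salt, 1448 without rmr6 Control, 1999 without rmr6 Drought, 1388 without rmr6 Salt and 1504 without rmr6 Drought+Salt. In that setting 10 of the 14 named genes passed in all 8 fits.

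Of the lists by symbol, cell cycle, replication and histone genes were lower in 10 of 36 cases under drought at T0 (adjusted p = 8.11e-05 by Fisher's exact test), and in 9 of 29 without 7 kinesins (adjusted p = 9.70e-05 by Fisher's exact test). The list with kinesins did not pass against genes at FPKM 5 or more (adjusted p = 0.110 by Fisher's exact test). Heat shock genes were higher in 6 of 23 cases (9.73e-04), with hsp18f at 1.64 (SE 0.234) and hsp18c at 1.70 (SE 0.240), abscisic acid signalling in 7 of 36 (0.00113), with PP2C4 at 1.57 (SE 0.156), and potassium and sodium carriers in 4 of 19 (0.0244), all as adjusted p by Fisher's exact test. Glutathione transferases were lower in 5 of 25 cases (adjusted p = 0.0356 by Fisher's exact test), gst14 by -0.99 (SE 0.109). Against genes at FPKM 5 or more the carriers (adjusted p = 0.219) and the glutathione transferases (0.234) did not pass Fisher's exact test, while the heat shock and abscisic acid lists did. These tests rest on the drought calls, which depended on every condition.

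For salt at T0 limma passed 0 genes (2307 at unadjusted p under 0.05). At T7 it passed 4 for drought (2924 unadjusted) and 1 for salt (4776 unadjusted). The 4 were GRMZM2G503264, GRMZM2G503318, GRMZM2G559379 and GRMZM2G566240, and the 1 was GRMZM2G491246, all named after their values were seen. These loci have 99 to 132 bp of exon and were listed at 0 in 4 of 8 conditions, and 0 genes passed for either stress at T7 without loci under 200 bp (2927 and 4815 at unadjusted p under 0.05 by limma).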

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

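The tests of differences between stress responses were all chosen after the data had been seen. They used limma on the condition values and assumed that the lone control varies like the stressed conditions. For the difference of the stress response between genotypes, 22 genes passed at T0 (959 at unadjusted p under 0.05) and 24 at T7 (1213 unadjusted). For the difference of the stress response between T7 and T0, 13 genes passed in wt (2401 unadjusted) and 18 in rmr6 (2811 unadjusted).

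Of these genes, 21 of 22, 22 of 24, 12 of 13 and 16 of 18 have under 200 bp of exon. With such loci left out, limma passed 0 genes for the difference between genotypes at T0 (659 at unadjusted p under 0.05), 1 at T7 (833), 1 for T7 against T0 in wt (2223) and 0 in rmr6 (2441). The 1 gene was GRMZM2G016655 in both cases, with log2 differences of 1.75 (adjusted p = 0.0129 by limma) and -1.55 (0.0434), named after its values were seen. In simulated data the difference between genotypes at T0 recovered 2.0% of changes of 1 log2 unit, so the few calls do not show that the responses were alike.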

How the results depend on the processing

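Chosen after the data were seen were the limma fits of stress against control, single stresses and differences between responses, the alternatives of these and of rmr6 against wt at T7, the fits without loci under 200 bp or with those too deep to estimate, the adjustment anew of the deposited p-values, folds taken from the median and folds of the table of all conditions; the other alternatives were planned. Of 161 alternative values 77 lay within 1.5 times the reported one and 84 did not. No paired analysis was possible because the deposited values combine the replicates of each condition. For the same reason the planned fits per library, without the kit term, with camera or fry and with robust eBayes were not run, and pairs with wt at T7 have no overlap at q of 0.01. Read depth is unknown, and so are its limits.

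At q of 0.01 or less the authors' calls were 998 in wt T0, 282 in rmr6 T0, 0 in wt T7, 82 in rmr6 T7 and 636 for rmr6 against wt. Among genes at FPKM 5 or more, which leaves fewer genes, they were 1221, 363, 283, 529 and 449. With a log2 fold of 1 or more in the table of all conditions 931 calls were left in wt T0, 152 in wt T7 and 292 in rmr6 T7. The transcript tables gave 1126, 340, 199 and 545 genes for the stress comparisons. By limma these were 23, 30, 15 and 31, and without loci under 200 bp 0 (3545 at unadjusted p under 0.05), 0 (3419), 2 and 1, and the cause was not tested. The 2 were GRMZM2G016655 and GRMZM2G142413_O_2 and the 1 was XLOC_062510, named after their values were seen.

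The genotype effect had 8180 genes at FPKM 5 or more, 5043 with T0 alone and 4588 with T7 alone, and 10792 to 11449 with a condition left out. For rmr6 against wt at T7 it was 2964 at FPKM 5 or more and 1293 to 2025 with a pair left out. The drought effect at T0 had 4342 genes without loci under 200 bp, and with a condition left out 1 to 561, or 823 to 3088 without such loci. The salt effect at T0 had 2 genes with a pseudocount of 0.1, 1 without drought in the model and 0 to 3 with a condition left out: 2 without wt Drought, 1 without wt Drought+Salt and 3 without rmr6 Salt. The drought effect at T7 had 9 with that pseudocount, 0 at FPKM 5 or more (2060 unadjusted by limma) and 0 without short loci (2927). It ranged from 0 to 8 with a condition left out: 0 without wt Salt, wt Drought+Salt or rmr6 Salt, 2 without rmr6 Control and 8 without rmr6 Drought+Salt. The salt effect at T7 had 7, 0 (3451) and 0 (4815) under the same settings. It ranged from 0 to 6: 0 without wt Control, wt Drought, wt Drought+Salt or rmr6 Drought, 6 without wt Salt or rmr6 Salt and 2 without rmr6 Drought+Salt. Differences between responses fell to 0, 1, 1 and 0 genes without loci under 200 bp. Some settings test fewer genes or use fewer conditions, and the cause of the changes was not tested for any setting.

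Against genes at FPKM 5 or more, 3 fixed lists passed in wt T0 and 0 in rmr6 T7. At q of 0.01 the genes higher in both were 145 for wt T0 and rmr6 T0, 4 for rmr6 T0 and T7, 37 for wt T0 and rmr6 against wt, 15 for rmr6 T0 and rmr6 against wt, and 0 for either genotype with drought, where 5 drought genes passed limma at 0.01. Of these 5, only 1 and 2 were higher and tested with wt and rmr6, so that overlap was all but fixed at 0. At 0.05 drought shared 312 genes higher with wt T0 (57.0 by chance) and 149 with rmr6 T0 (16.9 by chance), from the same libraries.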

Other observations

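The tests of the control values, of the chromosome intervals and of small RNA precursors below were chosen after those results had been seen; the tests of scaling, of the single control and of other splits were written beforehand.

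Under stress the authors called far more genes higher than lower, 1908 against 75 in wt at T0. With folds taken relative to their median, 58.5% of 2-fold differences were rises, against 83.8% without that step. This lies under the 60% set beforehand, so the scaling of the tables may account for part of the excess. Subtracting a positive median lowers the share of rises whatever raised the median, so the step cannot tell scaling from a broad rise in the plants. Of the authors' calls 1322 rises and 75 falls lay 1 log2 unit or more from the median, but these were called before that step, so falls it would add are not among them. Taking each stressed condition in turn as the single one gave a median of 64.8% of differences higher in the others, against 67.7% for the controls. The comparison of 1 value with 3 therefore stays open as well. These shares were counted otherwise than those that follow and can be set against each other alone. For the wt control at T7 they hold 1764 differences higher and 815 lower in the others, where the count below has 413 rises and 529 falls. Among genes at FPKM 1 or more on both sides in both kinds of table, 53.8% of 2-fold differences of wt at T0 were rises in the table of all conditions, against 84.6% in the comparison table, and 46.9%, 43.8% and 35.3% for rmr6 T0, wt T7 and rmr6 T7. The share depends on that limit: among tested genes at FPKM 1 or more on either side, with a pseudocount of 1, it was 63.1% for wt T0 (82.4% in the comparison table), and 57.1%, 48.75% and 47.1% for the others. The control values of the comparison tables lay lower than those of that table by an amount that varied from gene to gene, so a candidate explanation for part of the excess is how these control values were computed. Which table lies nearer to the plants is unknown, and no biological explanation was separated from these.

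The calls of rmr6 against wt at T0 gathered around nrpd1, with 12% of tested genes called in the interval of 10 Mb that holds it, against 2.77% elsewhere (p = 2.03e-10 by Fisher's exact test). A candidate explanation is a stretch of chromosome carried along with rmr6-1 from another line. An effect of the lost polymerase on this region stays open and was not tested.

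Small RNA precursors made up 25.8% of the genes higher in rmr6 outside the enriched intervals, against 12.8% of tested genes there (p = 2.70e-22 by Fisher's exact test). Those intervals, found from the same calls, held 16 and 9 of the genes called higher. They are too few to hold the whole excess, so leaving them out could hardly change the share. The interval between them had 13 of 182 tested genes called (adjusted p = 0.0803 by Fisher's exact test) and was counted as outside. Stretches from another line elsewhere, the choice of loci the authors added to the annotation, and values near 0 in wt stay open. That loss of RNA polymerase IV raises transcripts at such loci may be proposed as a hypothesis. It comes from these same data and was not itself tested.

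In 1 of 100 splits that swapped genotypes within conditions, the real one, limma called as many genes as the genotype effect (12751, the highest other 0). This is a share under 0.05, and the difference between genotypes was steady over the conditions. Swapping moves such a steady difference into the residual, so the other splits could hardly call genes. With 1 line per genotype and no spread between plants, the splits cannot exclude chance differences between the sets of plants. For rmr6 against wt at T7 the 8 splits were too few for a share under 0.05 (real 4588, highest other 0). The 18 splits for single stresses were too few as well. Without the other stress in the model, drought at T0 gave 3005 genes and the highest other split 7, with 1 split as large. Salt at T0 gave 1 gene in the real split, and 16 splits gave as many. The highest was the split by drought with 3005, the same count as given for drought, so it adds no support. At T7 drought gave 4 genes (8 splits as many, highest other 9) and salt 1 (15 splits as many, highest other 9).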
